A study of Homo sapiens with 9 samples.

How the data were processed

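RNA from 293 Flp-In T-REx cells, a human line, was sequenced in 9 libraries, 3 from the parental line, 3 from a line with inducible microRNAs against C6orf203 (silenced) and 3 from a line with the same microRNAs and a microRNA-insensitive, FLAG-tagged C6orf203 transgene (rescued). Total RNA from whole cells was depleted of nuclear-encoded rRNA, fragmented, copied with random primers and made into strand-specific dUTP libraries. The labels gave each group the replicate letters A, B and C. They did not say whether equal letters marked a shared day, whether replicates were separate cultures, or when and in which lines tetracycline was added.

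The authors deposited a table of counts per 1000000 reads (CPM) made with edgeR, together with a GENCODE basic annotation on GRCh38 in which mitochondrial features had been modified. Per the labels, reads were processed with FastQC 0.11.3, cutadapt 1.9.2, Trimmomatic 0.32, STAR 2.5.2b, HTSeq 0.9.1, DESeq2 1.16.1 and edgeR 3.18.1. The order of these steps, the rule for reads that overlapped several mitochondrial features and the filter that reduced the 58223 annotated genes to the 16125 in the table are not given in the sources used here. The table held 23 of the 41 annotated features of mitochondrial DNA (mtDNA), among them 5 tRNAs. Each column summed to 1000000, and within a tolerance of 1e-06 reads 100% of the values of each library were whole multiples of that library's smallest step. Multiplying by the library total recovered the reads, which differed from the deposited CPM by that factor alone.

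The choices in this paragraph were made before the data were examined. Genes with at least 1 CPM in at least 3 of the 9 libraries were tested, which kept 15646 genes and left out 479. The log2 of CPM plus 0.5 was fitted with limma 3.58.1 in R 4.3.3, with 3 group means, a mean-variance trend and robust empirical Bayes. The 3 comparisons were silenced against parental, silenced against rescued and rescued against parental, each two-sided. Benjamini-Hochberg adjustment was made per comparison over the genes tested, and an adjusted p under 0.05 was called changed. Genes called in the same direction in silenced against parental and against rescued were counted as changed against both controls. The percent of CPM on mtDNA was compared by exact two-sided permutation tests, for which 3 against 3 libraries allow no p below 0.1. A second choice fixed beforehand was the naming rule. It took C6orf203, the 2 highest and 2 lowest mtDNA-encoded mRNAs or rRNAs, the 8 largest changes per direction among called genes with a mean of at least 5 CPM and no overlap between the groups' libraries, and up to 4 called members per gene list. Features and genes whose changes are given outside that rule are marked where they appear.

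Lists of genes, 27 in all, were also fixed before the data were examined. They covered mtDNA-encoded mRNAs, rRNAs and tRNAs; complex I subunits; nuclear-encoded subunits of complexes II to V; mitoribosomal proteins; mtDNA transcription and maintenance; mitochondrial RNA processing and decay; and mitochondrial tRNA synthetases and translation factors. Further lists held integrated stress response genes, mitochondrial chaperones and proteases, interferon-stimulated genes, cholesterol synthesis, glycolysis, hypoxia response, p53 targets, cell cycle G1/S and G2/M genes and cytosolic ribosomal proteins. The remaining lists held the unfolded protein response of the endoplasmic reticulum, immediate early genes, small RNA silencing machinery, and extracellular matrix, kidney epithelial, neuronal, adrenal and blood cell markers. None of the 15 blood cell markers was in the tested genes, which left 26 lists. The lists were tested with camera in limma at a preset correlation of 0.01, adjusted over all lists and the 3 comparisons, and again with camera at an estimated correlation and with fry. Members were also counted after adjustment over the list alone.

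Depth and precision were as follows. Recovered reads ranged from 7528097 to 11909684 per library, and the median 95% confidence half-width of a log2 fold change was 0.34. On simulated data made from the recovered reads, limma called 78.6% of genes set to a log2 fold of 1 and 19.5% of those set to 0.5 in the silenced against parental layout. In the silenced against rescued layout it called 71.0% and 19.7%. In the rescued against parental layout it called 71.0% and 25.0%. Of the 15446 genes simulated without a change, 12, 11 and 6 were called. Each layout held the same number of changed genes, whereas limma called 2446, 3 and 1381 genes in the real comparisons. The adjusted threshold depends on how many genes change. The shares called therefore do not measure the power of the real comparisons, and may be too high for silenced against rescued. Libraries of unchanged groups were simulated 50 times to show what the shared groups alone give to overlaps between comparisons.

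Alternatives covered the pseudocount, the low-value filter, TMM, median-of-ratios and quantile scaling, scaling without mtDNA reads, a block for the replicate letter, library quality weights, the 2 groups compared alone, a constant prior variance, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, stricter thresholds, and each library left out in turn. For the mtDNA share they covered the features counted and the denominator. Chosen after the data had been seen were the omission of replicate C of both engineered lines, the 2 groups with a block, the estimated correlation with a block, the sums over light-strand features, and random thinning of all libraries to the number of reads of the shallowest. Replicate letters were taken to pair libraries of a pair of groups only where the deviations from the group means correlated above 0.1 across genes for every letter. This held for silenced and rescued (0.47, 0.16 and 0.58 for A, B and C, although silenced B reached 0.27 with another letter) and not for the other comparisons. The choice to pair came from these correlations. The labels do not state a pairing, although the deposited sample numbers pair silenced and rescued libraries by letter. GC content and transcript length came from GENCODE transcript sequences of the same build. No library was left out of the main comparisons.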

Results

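The transcriptome of 293 Flp-In T-REx cells, a derivative of the human HEK293 kidney line with an integration site for transgenes and a tetracycline repressor, was measured by strand-specific RNA sequencing. The stated aim was the influence of C6orf203 silencing on mitochondrial transcripts. C6orf203, also named MTRES1, encodes a mitochondrial RNA-binding protein. There were 3 groups of 3 libraries. The parental cells carried no construct against C6orf203, the silenced cells carried inducible microRNAs against it, and the rescued cells carried the same microRNAs and a microRNA-insensitive C6orf203-FLAG transgene. Replicates A, B and C held 10180490, 11909684 and 11356030 reads in the parental group. They held 9901414, 11332103 and 7528097 reads in the silenced group, and 9394327, 10397240 and 10790925 in the rescued group. The mtDNA-encoded large rRNA, MT-RNR2, took from 19.8% to 26.1% of the reads of a library. Values are given as counts per 1000000 reads (CPM), with the standard deviation (SD) of n = 3 libraries per group.

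C6orf203 RNA was lower in silenced cells and higher in rescued cells than in the parental line. The gene (ENSG00000130349.9, GRCh38 chromosome 6, 107028213 to 107051342, plus strand) stood at 9.27 ± 3.11 CPM (SD, n = 3) in parental, 3.58 ± 0.297 in silenced and 41.2 ± 4.40 in rescued libraries. The silenced mean was 61.3% below the parental mean. The rescued mean was 4.45 times the parental and 11.5 times the silenced mean. The 3 groups did not overlap, and the reads behind the values were 69 to 152, 29 to 37 and 390 to 433 per library. In limma the log2 fold change was -1.21 in silenced against parental (SE 0.19, adjusted p = 0.0019), -3.35 in silenced against rescued (adjusted p = 4.9e-07) and 2.14 in rescued against parental (adjusted p = 7.8e-05). Reads of the transgene can be counted to the same gene, so the rescued value does not separate transgene from endogenous RNA.

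**Figure D1:**
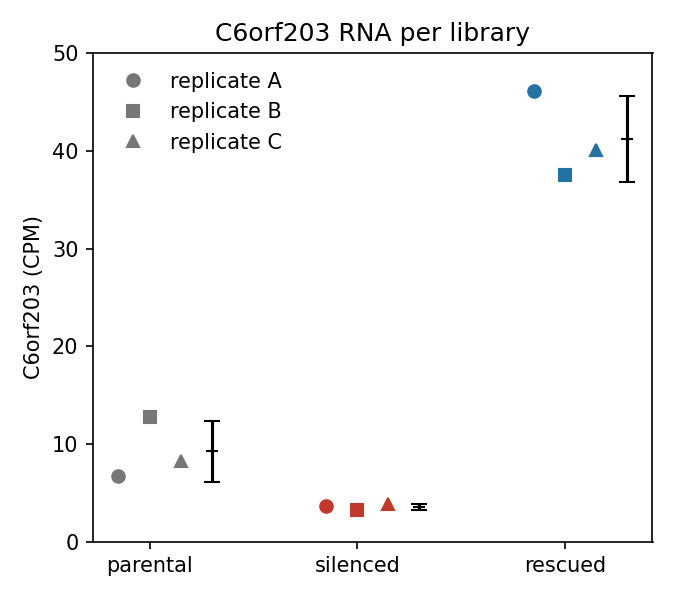
C6orf203 level in CPM in each library by group. Points are libraries, marker shapes are replicate letters, and black bars are the mean ± SD of n = 3; silenced libraries lay at 3.27 to 3.85 CPM and rescued libraries at 37.5 to 46.1 CPM.

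The respiratory chain mRNAs that mtDNA encodes showed no change past the threshold in silenced against parental cells. MT-CYB, the cytochrome b of complex III, was at 1175 ± 108 CPM in silenced and 997 ± 39.6 in parental libraries (log2 0.23, n = 3). MT-ND6, the complex I subunit encoded on the light strand, was at 78.0 ± 7.86 against 102 ± 21.0 CPM (log2 -0.37, adjusted p = 0.13). MT-ND2 had a log2 fold change of -0.11 and the joint feature MT-ND4L_ND4 one of 0.23. The rRNAs MT-RNR1 and MT-RNR2, named after their values were seen, had log2 fold changes of 0.23 and 0.08. The 13 mRNAs were counted as 11 features, and in limma 0 of 11 passed the threshold over all genes and 0 adjusted over the list alone. At unadjusted p under 0.05 there was 1, MT-ND6. On the recovered reads edgeR called 0 and DESeq2 called 1, MT-ND6, as limma did with library quality weights. The 95% intervals of the 11 features together ran from -0.72 to 0.53 on the log2 scale, so folds below 0.609 or above 1.44 lay outside them. The median of the list was 0.04, and it turned to -0.02 with TMM or median-of-ratios scaling. Of the 2 rRNAs and 4 tRNAs measured 0 passed, also adjusted over the list alone, and camera in limma called none of the 3 lists (adjusted p = 0.82, 0.90 and 0.12).

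Transcripts of the light strand from the mtDNA control region fell in silenced against parental cells. The region holds the promoters of both strands. 7SRNA_L, the 7S RNA transcribed from the light-strand promoter (mtDNA 217 to 407, minus strand), was at 59.7 ± 2.89 CPM in silenced and 93.0 ± 23.3 in parental libraries (log2 -0.60, SE 0.15, limma adjusted p = 0.019, n = 3). D-loop_L, the annotated feature for that strand of the control region, was at 24.4 ± 5.69 against 38.2 ± 6.17 CPM (log2 -0.65, SE 0.18, adjusted p = 0.028). These were the 2 called features of the 22 mtDNA features tested. Others had a lower mean without passing, the light-strand tRNA-like feature (log2 -0.55, adjusted p = 0.083), MT-ND6 and the heavy-strand feature D-loop_H (-0.28, adjusted p = 0.079), which were named after their values were seen, so the change is not shown to be limited to 7SRNA_L and D-loop_L. The neighbouring tRNA MT-TP was at 5.44 ± 0.701 against 7.56 ± 0.164 CPM, a log2 fold change of -0.45 (adjusted p = 0.074). In rescued cells 7SRNA_L stood at 78.8 ± 4.32, D-loop_L at 31.5 ± 5.44 and MT-TP at 7.96 ± 1.07 CPM. Against rescued, the log2 fold changes in silenced were -0.40, -0.37 and -0.51, none past the threshold in limma (adjusted p = 0.87 each) or with the replicate block (adjusted p = 0.32, 0.26 and 0.31). In a fit of these groups alone with the block, chosen after the results were seen, 7SRNA_L passed and the others did not (adjusted p = 0.0055, 0.070 and 0.10). With library quality weights 7SRNA_L and MT-TP passed (7SRNA_L, silenced vs rescued, 0.023, and MT-TP, silenced vs rescued, 0.046). These 3 features were singled out after their values were seen. In silenced against parental the 7SRNA_L call was lost without parental A, parental B or silenced B (7SRNA_L, silenced vs parental, limma adjusted p = 0.085, 0.096 and 0.066) and the D-loop_L call without parental A, parental B or silenced C (D-loop_L, silenced vs parental, 0.090, 0.12 and 0.093), and over the alternatives their adjusted p ranged from 4.7e-06 to 0.096 and from 0.00016 to 0.12. With TMM scaling MT-TP passed (MT-TP, silenced vs parental, 0.039). Their summed level was 89.6 ± 7.05 CPM in silenced, 139 ± 29.6 in parental and 118 ± 2.72 in rescued libraries (exact permutation p = 0.1 against each, the smallest that 3 against 3 allow).

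Between silenced and rescued cells no difference in mtDNA-encoded mRNAs passed either. MT-CO2, a subunit of complex IV, was at 1626 ± 161 CPM in silenced and 2070 ± 426 in rescued libraries (log2 -0.33, limma adjusted p = 0.87, n = 3). MT-ND1, a complex I subunit, was at 477 ± 36.7 against 441 ± 28.6 CPM, the highest value at a log2 fold change of 0.11. In limma 0 of 11 features passed in silenced against rescued, 0 adjusted over the list alone and 1 at unadjusted p under 0.05, with 0 called by edgeR and by DESeq2. The block for the replicate letter gave 0, and 1, MT-CO2, in a fit of these groups alone, as did library quality weights. The intervals ran from -0.64 to 0.38. The tRNAs MT-TP and MT-TW passed when adjusted over the list alone (2 of 4 measured tRNAs), with log2 fold changes of -0.51 and -1.08, and were named after their values were seen. MT-TW lay near the detection limit, at 0.714 ± 0.213 CPM in silenced and 2.24 ± 1.35 in rescued libraries. In rescued against parental, MT-CO2 had a log2 fold change of 0.38 (adjusted p = 0.11) and MT-RNR1 one of 0.40 (adjusted p = 0.12). There 0 of 11 mRNA features passed in limma, 0 over the list alone and 1 at unadjusted p under 0.05, and edgeR and DESeq2 called 0. No mtDNA feature was called in limma in silenced against rescued or in rescued against parental. Transcripts of mtDNA made up 23.8 ± 1.52% of CPM in parental, 25.3 ± 1.54% in silenced and 26.6 ± 3.52% in rescued libraries. The exact permutation p was 0.3 for silenced against parental, 0.8 for silenced against rescued and 0.3 for rescued against parental. The difference of -1.24 points between silenced and rescued turned to 0.788 without rescued replicate C.

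**Figure D2:**
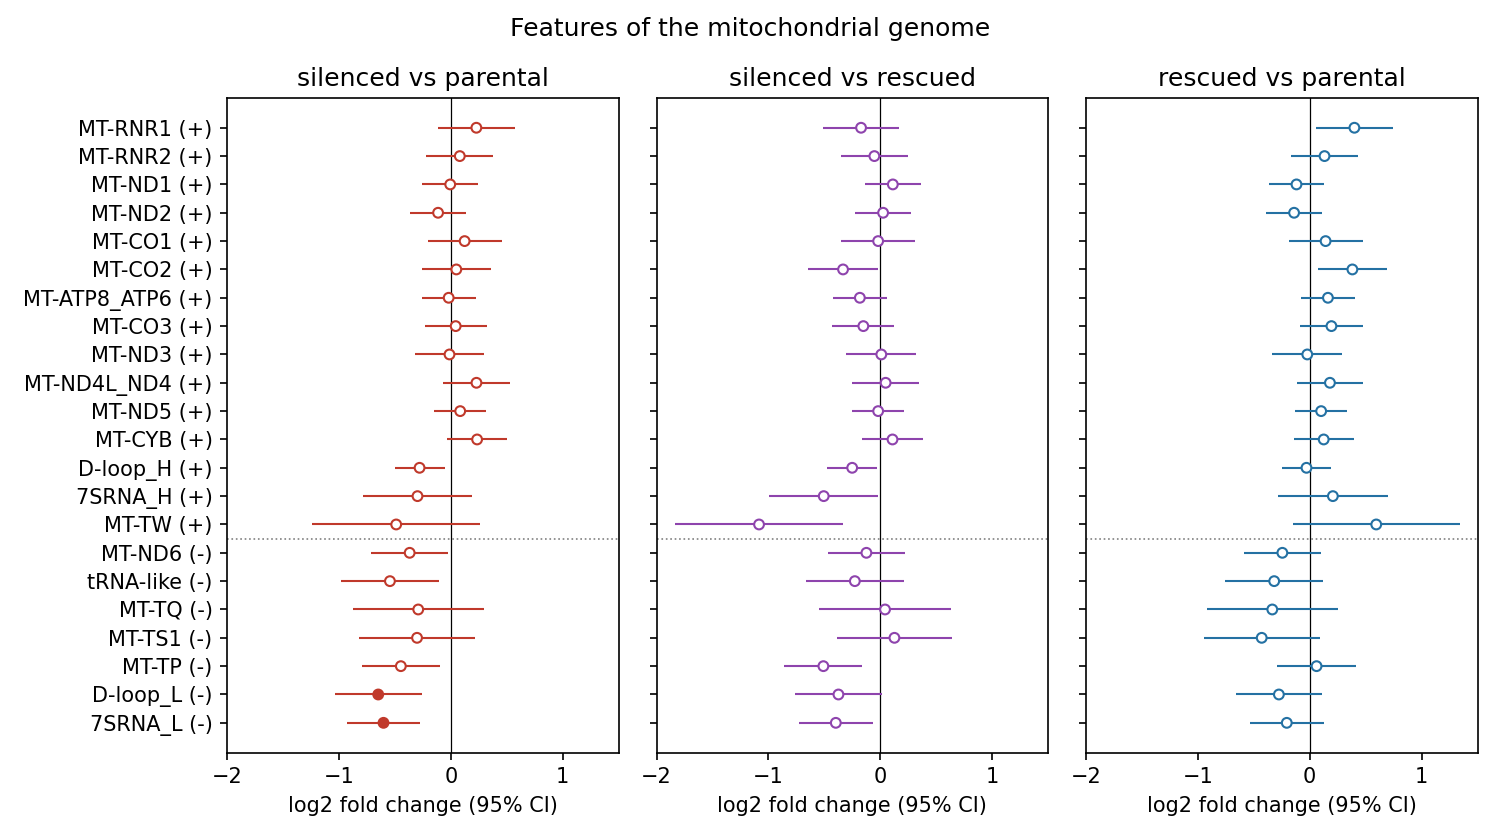
Log2 fold change of each of the 22 tested mtDNA features, with 95% confidence intervals, in the 3 comparisons (strand in brackets, n = 3 per group). Filled points passed an adjusted p of 0.05, which were 7SRNA_L and D-loop_L in silenced against parental; the dotted line separates plus from minus strand features.

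Against the rescued line, which shares the microRNAs, limma called 3 genes in silenced cells, a count that depended on how the replicate letters were fitted. The rescued mean of C6orf203 was 4.45 times the parental one. The comparison therefore does not separate silencing from a raised level or from other differences between the 2 lines. CEBPE, a myeloid transcription factor of the C/EBP family, fell to 6.92 ± 0.428 CPM from 18.5 ± 2.37 in rescued libraries (log2 -1.35, SE 0.14, limma adjusted p = 0.0011, n = 3). CNTN1, a neuronal cell adhesion molecule, rose to 26.9 ± 0.873 from 12.03 ± 2.85 CPM (log2 1.15, SE 0.17, adjusted p = 0.044). With C6orf203 these were the 3 genes called in limma, 1 higher and 2 lower, of 868 at unadjusted p under 0.05. DESeq2 called 7 and edgeR 2. In 50 simulations without any change, or any deviation shared between libraries, limma called a mean of 0.58 and at most 4 genes. Since letters A, B and C paired silenced and rescued libraries, a block for the letter was also fitted, and it called 22 genes, 15 higher and 7 lower. The same block in a fit of these 2 groups alone, chosen after the results were seen, called 284, 191 higher and 93 lower. Among the 22 were LCP1, an actin-bundling protein (log2 0.88), HSPA13, an HSP70 family member (0.67), and GK, the glycerol kinase (-0.55), which were chosen after their values were seen. Against parental, LCP1 was not called in silenced (log2 -0.13, limma adjusted p = 0.66) and was lower in rescued cells (-1.01, adjusted p = 0.0067). HSPA13 was called in neither line (0.32 and -0.35), and GK in silenced only (-0.49, adjusted p = 0.012). The count of genes in silenced against rescued was 872 with library quality weights and 10 without replicate C of both lines. The call of CNTN1 was lost in 15 alternatives, among them TMM (adjusted p = 0.157 in limma, over a range of 2.0e-06 to 0.458), edgeR and the omission of any parental library, silenced A or B, or rescued A or B (adjusted p from 0.0573 without parental C to 0.458 without silenced B).

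The same genes were called in the same direction against the parental line, so 3 genes changed in silenced cells against both controls. CEBPE was at 23.3 ± 3.10 and CNTN1 at 11.8 ± 2.20 CPM in parental libraries (n = 3), and their log2 fold changes against parental were -1.68 and 1.17 (limma adjusted p = 4.3e-05 and 0.0013). Between rescued and parental, CEBPE and CNTN1 had log2 fold changes of -0.33 and 0.01, not called, and C6orf203 rose. Both comparisons use the same silenced libraries, and 50 simulations without any change gave a mean of 0.08 and at most 1 such gene. The simulated libraries held no deviation shared by replicate C of both engineered lines, so these values do not cover that structure of the samples. Among 20 splits that keep the parental libraries together, a split other than the real one gave up to 266 genes. C6orf203, 1 of the 3 genes, was the target itself. The independent expectation was 0.105 higher and 0.102 lower. Part of an overlap may come from the shared libraries, and the excess is not read as a shared effect. With the replicate block the count was 16, 11 higher and 5 lower, with library quality weights it was 481, and without replicate C of both engineered lines it was 5.

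No member of a fixed list was called in silenced against rescued over all genes, except that adjusted over the list alone the matrix protein SPARC (log2 -0.58) and the tRNAs MT-TP and MT-TW passed, all named after their values were seen. Integrated stress response genes had a median log2 difference of 0.21, positive in 30 of 31 members. Complex I subunits had a median of -0.09, complex II to V subunits of -0.13, mitoribosomal proteins of -0.09, cytosolic ribosomal proteins of -0.05 and mtDNA-encoded tRNAs of -0.23. These 6 lists passed camera at the preset correlation (limma adjusted p from 7.7e-07 to 0.012), and each had adjusted p = 0.83 with an estimated correlation. With the replicate block p53 targets also passed at the preset correlation (adjusted p = 0.046, and 0.056 without the block), and not with an estimated correlation and the block (0.57). Calculated without silenced replicate C, the calls of complex I, complexes II to V, mitoribosomal proteins and the stress response were lost (limma adjusted p = 0.97, 0.79, 0.79 and 0.67), and without rescued replicate A those of complex I and the stress response (0.14 and 0.078). The count of lists was 10 without silenced A, 10 without rescued B and 12 without rescued C.

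Against the parental line, the stress-induced genes CHAC1 and DDIT3 rose and SPRY4 and HSPA8 fell in silenced cells. Neither here nor for the mtDNA features above does the comparison with the parental line separate C6orf203 silencing from line history, exposure or preparation. CHAC1, a glutathione-degrading enzyme induced by ATF4, rose from 2.44 ± 0.357 to 29.5 ± 5.46 CPM (10.2-fold, limma adjusted p = 0.00064, n = 3). DDIT3, the stress transcription factor CHOP, rose from 4.34 ± 0.760 to 18.1 ± 7.10 CPM (3.70-fold, adjusted p = 0.00045), and TXNIP, an inhibitor of thioredoxin, from 11.3 ± 1.34 to 40.8 ± 4.44 CPM (3.49-fold, adjusted p = 1.1e-05). SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, fell from 14.3 ± 0.651 to 2.45 ± 0.948 CPM (0.192-fold, adjusted p = 7.6e-05). HSPA8, the constitutive cytosolic HSP70 chaperone, fell from 1462 ± 195 to 470 ± 116 CPM (0.317-fold, adjusted p = 0.0015).

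Other genes with the largest rises were the collagen receptor DDR2 (log2 3.44, at 39.6 ± 29.8 against 2.66 ± 0.678 CPM), the cAMP-activated exchange factor RAPGEF3 (2.80), the pseudogene ASNSP1 (2.29), XKR5 (2.25) and the mitochondrial folate enzyme ALDH1L2 (1.95). ASNSP1 resembles ASNS, which was named after its value was seen and had a log2 fold change of 0.97 that did not pass (limma adjusted p = 0.18). The call of RAPGEF3 was lost without parental A, B or C (RAPGEF3, silenced vs parental, limma adjusted p = 0.096, 0.077 and 0.0502). The largest falls were those of the ETS transcription factors ETV1 (-2.01) and ETV5 (-1.60), CEBPE (-1.68), the transcriptional repressor NACC1 (-1.58), the teneurin TENM1 (-1.51) and the methionine salvage enzyme ADI1 (-1.48). In all, 2446 of 15646 genes changed in limma, 1650 higher and 796 lower, and 420 changed at least 2-fold, 378 of them higher. The share higher depended on scaling, at 67.5% with library totals and 49.3% (1383 higher, 1425 lower) with TMM. The count fell to 1118, 1004 and 1344 without parental A, B and C and to 1444 and 1100 without silenced B and C, and was 6286 with library quality weights.

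The integrated stress response, which reduces translation and induces ATF4 targets, was the list with the most rises. Of 31 measured genes 20 rose and 1, the tryptophanyl-tRNA synthetase WARS (log2 -0.37), fell, or 21 and 1 adjusted over the list alone, with a median log2 fold change of 0.88. Beside CHAC1 and DDIT3, the cystathionine lyase CTH rose from 11.6 ± 1.32 to 30.7 ± 3.82 CPM (n = 3, limma adjusted p = 0.00023), and STC2 rose by 1.42 and JDP2 by 1.68 on the log2 scale. ATF4 itself rose from 245 ± 18.7 to 440 ± 50.8 CPM. ATF4 and WARS were named after their values were seen, and the call of WARS was lost without parental A or B or any of the silenced libraries (WARS, silenced vs parental, limma adjusted p from 0.054 to 0.0996). Camera in limma called the list (adjusted p = 1.3e-11 at the preset correlation, adjusted p = 0.83 with an estimated correlation). Without replicate C of both engineered lines 21 members rose and 1 fell.

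A minority of the nuclear-encoded genes for mitochondrial gene expression fell in silenced cells. Of 81 mitoribosomal proteins 24 fell and 0 rose, and 40 fell adjusted over the list alone; the median log2 fold change was -0.40. MRPL45 fell from 20.1 ± 2.12 to 12.4 ± 1.06 CPM (n = 3, limma adjusted p = 0.0066), and MRPL42 (-0.65), MRPL52 (-0.76) and MRPL39 (-0.69) fell as well. For mitochondrial RNA processing and decay 8 of 37 fell and 0 rose (11 adjusted over the list alone). FASTKD5, which processes mitochondrial precursor RNA, fell to 0.496-fold (adjusted p = 0.0014), and FASTKD2 (-0.53), the rRNA methyltransferase MRM3 (-0.62) and the tRNA 3' end nuclease ELAC2 (-0.75) also fell. For mtDNA transcription and maintenance 4 of 25 fell and 0 rose, also 4 adjusted over the list alone, and 10 had a log2 fold change above 0. TFAM, which packages mtDNA and activates its promoters, fell from 152 ± 3.96 to 95.3 ± 15.8 CPM (adjusted p = 0.0067), as did MTERF3 (-0.60), the elongation factor TEFM (-0.46) and the single-strand binding protein SSBP1 (-0.61). Among mitochondrial tRNA synthetases and translation factors 7 of 35 fell and 1 rose (11 and 1 adjusted over the list alone), with LARS2 at -0.62, GUF1 at -0.53, MARS2 at -0.49 and the release factor family member C12orf65 at 0.53. The calls of FASTKD2, MRM3, ELAC2, MTERF3, TEFM, SSBP1, MARS2 and C12orf65 were each lost without 1 or more of the parental and silenced libraries, and those of SSBP1 (rescued B) and TEFM (rescued A or B) also without a rescued one (limma adjusted p from 0.051 to 0.15). None of these 4 lists passed camera in limma with an estimated correlation (adjusted p = 0.83 with an estimated correlation for each). Against 10000 lists matched on GC content, length and level, the medians of mitoribosomal proteins and of mitochondrial RNA processing lay at percentile 0, and that of mtDNA transcription and maintenance (-0.14) at percentile 5.3, within the range from -0.17 to 0.14 that held 95% of them.

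In the other nuclear-encoded mitochondrial lists, of chaperones and respiratory chain subunits, few members passed. Of 20 mitochondrial chaperones and proteases 4 fell and 0 rose (4 adjusted over the list alone), among them HSPD1 (-0.70), HSPA9 (-0.54), GRPEL1 (-0.65) and DNAJA3 (-0.37). Of 39 complex II to V subunits 2 fell, ATP5F1 (-0.49) and UQCRFS1 (-0.47), and 0 adjusted over the list alone. The calls of HSPD1, HSPA9, DNAJA3, ATP5F1 and UQCRFS1 were lost without parental A, B or C or silenced C, and in part without silenced A or B or rescued A or B (limma adjusted p from 0.052 to 0.17). Of 36 complex I subunits 0 passed, also adjusted over the list alone, with a median of -0.19. All of the 7 nuclear mitochondrial lists passed camera in limma at the preset correlation (adjusted p from 4.7e-17 to 0.022) and each had adjusted p = 0.83 with an estimated correlation. Replicate C of the silenced line stood apart here, with a median 0.39 lower for mitoribosomal proteins and 0.45 lower for complex I than replicates A and B on the log2 scale. Without replicate C of both engineered lines 29 mitoribosomal genes fell and the median was -0.27, and complex I no longer passed (limma adjusted p = 0.096 without the 2 C libraries of the engineered lines and 0.077 without silenced replicate C). The call of mtDNA transcription and maintenance was lost without parental replicate B (0.060).

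**Figure D3:**
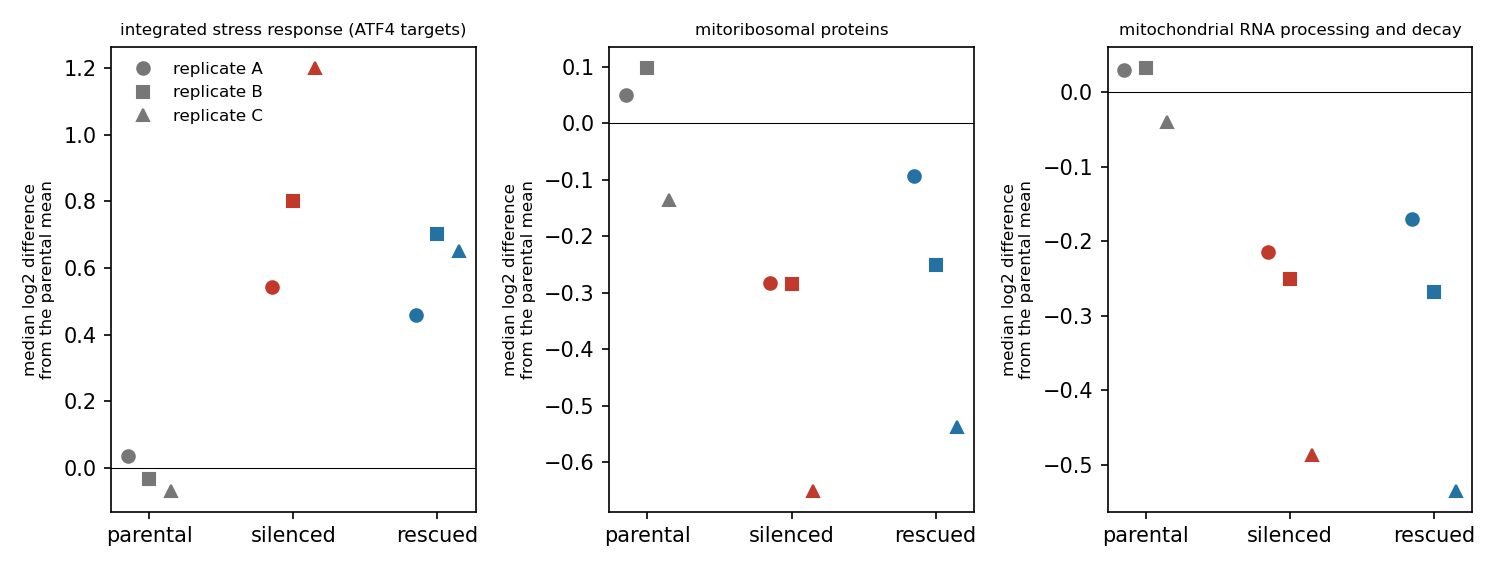
Median log2 difference from the parental mean over the members of 3 fixed lists, per library (points, with marker shapes for replicate letters). The stress response list lay higher, and the mitochondrial RNA processing list lower, in every silenced and rescued library than in the parental ones; the mitoribosomal list lay lower too, except that rescued A lay above parental C. The group medians of fold changes were 0.88 and 0.66, -0.40 and -0.31, and -0.28 and -0.34 for silenced and rescued.

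Lists on the endoplasmic reticulum, the cell cycle and the extracellular matrix held called genes in silenced against parental cells. In the unfolded protein response of the endoplasmic reticulum 5 of 20 fell and 2 rose (7 and 3 adjusted over the list alone). The chaperones HSPA5 (-0.73) and CANX (-0.59) and the co-chaperone DNAJC3 (-0.74) fell, and HERPUD1, a factor of protein degradation at the reticulum, rose (0.79). Of 30 G1/S genes 3 fell and 2 rose (3 and 2 over the list alone), with FEN1 at -0.66, CDC25A at -0.50, GINS3 at -0.38 and CDT1 at 0.78. Of 30 G2/M genes 1 fell, cyclin A2 (CCNA2, -0.52), also 1 adjusted over the list alone. Of 11 extracellular matrix markers 3 rose, the collagens COL5A1 (1.02), COL6A1 (0.71) and COL6A2 (0.96), also 3 over the list alone. The calls of FEN1, CDC25A, GINS3, CDT1, CCNA2, COL6A1 and COL6A2 were each lost without 1 or more of parental A, B and C, silenced B and C and, for GINS3, rescued B (limma adjusted p from 0.051 to 0.14), and that of COL6A2 also with TMM (COL6A2, silenced vs parental, 0.052). These 4 lists passed camera in limma at the preset correlation (adjusted p = 0.015, 0.011, 0.027 and 0.015), each with adjusted p = 0.83 with an estimated correlation. The G1/S, G2/M and matrix calls were lost without silenced replicate C (0.16, 0.076 and 0.065) and without the 2 C libraries of the engineered lines (0.18, 0.089 and 0.056). The G1/S call was also lost without parental replicate B (0.25), and the G2/M call without parental replicate A (0.13) or without parental replicate C (0.17).

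Among lists that camera did not call in silenced against parental, members passed in both directions. Of 20 p53 targets 7 rose and 1 fell (7 and 1 adjusted over the list alone). The cell cycle inhibitor CDKN1A (1.05), the apoptosis factor BBC3 (1.15) and the repair factor DDB2 (0.65) rose, and TIGAR, a regulator of glycolysis, fell (-0.79). Of 23 immediate early genes 6 rose and 5 fell (8 and 5 over the list alone), with ATF3 (1.04) and IER2 (0.70) higher and the phosphatase DUSP5 (-1.29) lower beside SPRY4. Of 18 hypoxia response genes 3 rose, VEGFA (1.12), PDK1 (0.55) and RORA (0.51), and BNIP3 fell (-0.55), against 5 and 2 over the list alone. The Argonaute AGO4 (0.60) and its partner TNRC6C (0.54) rose and TARBP2 (-0.53) fell among 13 small RNA silencing genes (3 and 3 over the list alone), whose median was 0.02 while the camera direction was down. Single genes rose among interferon-stimulated genes (DDX60, 1.09, of 15; 1 over the list alone), cholesterol synthesis (SREBF2, 0.72, of 23; 1) and glycolysis (ENO2, 0.54, of 22; 0). Of 77 cytosolic ribosomal proteins RPL3 rose (0.45) and RPL26 fell (-0.37), and 0 passed over the list alone. The calls of DDB2, PDK1, RORA, AGO4, TNRC6C, TARBP2, DDX60, ENO2, RPL3 and RPL26 were each lost without 1 or more of the parental and silenced libraries (limma adjusted p from 0.0502 to 0.14). Camera at the preset correlation gave these 8 lists, in limma, adjusted p from 0.26 to 0.85.

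Markers of kidney and other identities changed in single members. SIX2 (0.77), CDH1 (0.91) and CUBN (0.73) rose among 12 kidney epithelial markers (3 over the list alone). Of 8 neuronal markers 3 rose, NEFL (0.91), NCAM1 (0.43) and MAP2 (1.36), and 2 fell, SYP (-0.73) and INA (-0.70), against 4 and 2 over the list alone. MAP2 was named after its value was seen. GATA3 (0.55) rose among 3 adrenal markers (2 over the list alone). The calls of SIX2, CDH1, CUBN, NCAM1, MAP2 and GATA3 were each lost without 2 or more of parental A, B and C and silenced B and C, and that of MAP2 also without rescued B (limma adjusted p from 0.0501 to 0.13). Camera in limma called none of these 3 lists (adjusted p = 0.63, 0.61 and 0.40).

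Rescued cells, although their C6orf203 RNA was above the parental level, differed from the parental line in many of the same genes. This comparison does not separate the microRNAs, the transgene and line history from any difference in exposure or preparation. CHAC1 rose to 24.0 ± 13.5 CPM (7.29-fold, limma adjusted p = 0.0021, n = 3), DDIT3 to 14.2 ± 1.61 (3.05-fold) and TXNIP to 32.5 ± 2.0 (adjusted p = 7.5e-05). CCND1, the cyclin D1 of G1 progression, fell from 108 ± 10.5 to 42.9 ± 3.63 CPM (log2 -1.32, adjusted p = 0.00035). HSPA8 fell to 608 ± 207 CPM (log2 -1.31).

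Further large rises were those of DDR2 (log2 3.22), FREM1 (1.75), ASNSP1 (1.69) and the dynein heavy chain DNAH17 (1.5). The call of ASNSP1 was lost without parental A or B or rescued B or C (ASNSP1, rescued vs parental, limma adjusted p from 0.057 to 0.078) and that of DNAH17 without parental A or C, silenced B or any rescued library (DNAH17, rescued vs parental, 0.056 to 0.20). Further large falls were those of ETV5 (-1.70), SPRY4 (-1.66), TENM1 (-1.57), NACC1 (-1.54), ETV1 (-1.54) and the protein kinase A subunit PRKAR1B (-1.32). Limma called 1381 genes, 792 higher and 589 lower, and 231 changed at least 2-fold. The count was 517, 572 and 487 without parental A, B and C, 514 and 862 without rescued B and C, 2378 without silenced C, 2584 without replicate C of both engineered lines, 3922 with library quality weights and 828 with a constant prior variance.

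The fixed lists of rescued against parental followed. Of 31 integrated stress response genes 15 rose and 0 fell (19 and 1 adjusted over the list alone), among them CTH (1.07) and ATF3 (0.96), with a median of 0.66. Of 81 mitoribosomal proteins 9 fell and 0 rose (11 over the list alone), among them MRPL42 (-0.87) and MRPL39 (-0.87). For mitochondrial RNA processing and decay 7 of 37 fell (13 over the list alone), with FASTKD2 at -0.63, FASTKD5 at -0.56, the nuclease PDE12 at -0.55 and the RNA granule protein GRSF1 at -0.47. TFAM (-0.72, limma adjusted p = 0.0077), MTERF3 (-0.69) and TEFM (-0.54) fell among 25 genes of mtDNA transcription and maintenance (3 over the list alone). The translation factors GFM1 (-0.66) and GUF1 (-0.50) and LARS2 (-0.61) were among 4 of 35 that fell, and C12orf65 (0.51) rose (8 and 1 over the list alone). CLPX (-0.41) and GRPEL1 (-0.51) fell among 20 chaperones and proteases (6 fell and 1 rose over the list alone). DNAJC3 (-0.84), HSPA5 (-0.63) and CANX (-0.56) fell and HERPUD1 (0.51) rose among 20 genes of the unfolded protein response (5 and 1 over the list alone). COL5A1 (0.75) and SPARC (0.65) rose among 11 matrix markers (4 over the list alone). Of 30 G1/S genes 0 passed over all genes, and 7 fell and 2 rose over the list alone. Of 77 cytosolic ribosomal proteins 0 passed either way, with a median of 0.11. The calls of FASTKD2, FASTKD5, PDE12, GRSF1, MTERF3, TEFM, GUF1, LARS2, C12orf65, CLPX, GRPEL1, CANX, HERPUD1 and SPARC were each lost without 1 or more of the parental and rescued libraries and silenced B (limma adjusted p from 0.0501 to 0.16). Against matched lists the medians of mitoribosomal proteins and mitochondrial RNA processing lay at percentile 0 and that of mtDNA transcription at percentile 6.4. These 10 lists passed camera in limma at the preset correlation (adjusted p from 2.0e-10 to 0.049), each with adjusted p = 0.83 with an estimated correlation. The count of lists was 5 without rescued replicate C, where chaperones (0.069), the unfolded protein response (0.058), mtDNA transcription (0.053), cytosolic ribosomal proteins (0.070) and G1/S genes (0.13) no longer passed. The unfolded protein response was also lost without parental replicate A (0.075), without parental replicate B (0.060), without parental replicate C (0.059), without silenced replicate B (0.053) and without rescued replicate A (0.057), as were cytosolic ribosomal proteins without parental C (0.17) or rescued A (0.10), mtDNA transcription without parental B (0.10), and G1/S without parental B (0.21) or without the 2 C libraries of the engineered lines (0.15).

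Lists that camera did not call in rescued against parental also held called members, in both directions. CDKN1A (1.09), BBC3 (1.01), DDB2 (0.70) and GADD45A (0.79) were among 5 of 20 p53 targets that rose (9 rose and 2 fell adjusted over the list alone). Of 23 immediate early genes 5 rose and 3 fell, SPRY4, DUSP5 (0.5-fold) and DUSP6 (-0.86) being the lower ones (7 and 5 over the list alone). VEGFA (0.77), IFIT1 (0.97), SREBF2 (0.48), ENO2 (0.58) and NEFL (0.68) rose, each as the single higher member of its list. BNIP3 (-0.40), CCNA2 (-0.48), EPCAM (-0.46), INA (-0.76) and SYP (-0.60) fell. The calls of DDB2, GADD45A, IFIT1, SREBF2, ENO2, NEFL, BNIP3, CCNA2, EPCAM and SYP were each lost without 1 or more of the parental and rescued libraries and silenced B (limma adjusted p from 0.052 to 0.15). Complex I and complex II to V subunits had 0 called members, with medians of -0.11 and -0.08, the latter 0.01 with quantile normalization. The small RNA silencing, adrenal, mtDNA-encoded rRNA and mtDNA-encoded tRNA lists had 0 called members over all genes. Adjusted over the list alone, small RNA silencing genes had 1 higher and 3 lower, kidney markers 2 and 1, neuronal markers 3 and 2, hypoxia genes 1 and 1, and G2/M genes 0.

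The differences of both engineered lines from the parental line overlapped. Of the genes called in each, 686 were higher in both, where independent draws would give 83.5, and 400 were lower in both, against 29.97. CHAC1, DDIT3, TXNIP, SPRY4, ETV1, ETV5 and HSPA8 were among these shared genes, and C6orf203 was the 1 gene called in opposite directions. Both comparisons use the same parental libraries, and 50 simulations without any change gave a correlation of 0.48 (0.47 to 0.50) across genes and 0 shared calls, beside an observed correlation of 0.87. Part of the overlap may come from the shared parental libraries, which are too few to divide, and genes are not independent replicates. The simulations held no deviation shared by silenced and rescued libraries of a letter (correlations of 0.47, 0.16 and 0.58 for A, B and C). Their values do not cover that source. The covariance was 0.131 observed and 0.0195 simulated.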

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

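The tests on the lowered C6orf203 level, on shared exposure, on scaling of 7SRNA_L and D-loop_L, on library depth and numbers of reads, on a shared day, on silencing as the source of the light-strand values and on the rest of the light strand, and the splits that keep the parental libraries together, were chosen only after the results were seen, as were the light-strand features and sums that the tests of scaling per 1000 CPM and of the opposite strand use.

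C6orf203 had a log2 difference of -3.35 between the silenced and the rescued effect against parental, which singled it out because its effect differed between the engineered lines. CEBPE was singled out in the same way, at -1.35. CNTN1 was too, at 1.15.

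Integrated stress response genes were higher in both engineered lines than in the parental line. A lowered C6orf203 RNA level may not be the whole cause, since the list's median in rescued cells, where that RNA was above parental, was 75.6% of the median in silenced cells (whether the transgene's protein was functional was not measured). GC content and transcript length are argued against, because the median lay at percentile 100 of 10000 matched lists in both comparisons. Replicate C of the engineered lines was not needed, as 21 members in silenced and 17 in rescued rose without it. Exposure or handling shared by both engineered lines, for example to tetracycline, cannot be told apart from the microRNAs, which both lines carry: the median between the engineered lines was 0.21, and the labels do not give the exposure of each line.

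Transcripts of the light-strand side of the mtDNA control region were lower in silenced cells. Reads of the opposite strand are argued against, because the light-to-heavy ratio of the region was at least 5.57 times the MT-ND6 to MT-ND5 ratio in every library. Scaling to all reads is argued against for 7SRNA_L and D-loop_L in silenced against parental, as both stayed called with TMM, median-of-ratios, quantile and mtDNA-free scaling (adjusted p at most 0.0368, log2 -0.531 or lower). It stays open for the comparison with both other groups, judged on the sum of 7SRNA_L, D-loop_L and MT-TP. Per 1000 CPM of plus-strand transcripts this sum was 5.37 ± 0.838 in silenced and 6.76 ± 1.13 in rescued libraries (SD). The silenced mean was 79.4% of the nearer other mean, that of rescued. The exact permutation p was 0.3 against rescued, 0.1 against parental and 0.0833 against the 6 other libraries. Each silenced library lay below the rescued library of its letter, but rescued C, at 5.47, lay below silenced A and B. The letters are few, and the choice to pair them rested on correlations in the same data, so this order does not decide the question. The rest of the light strand also had a lower mean, 5.51 against 7.75 in parental and 5.92 in rescued libraries per 1000 CPM (exact permutation p = 0.1 and 0.6). The lowered C6orf203 level may lie behind the pattern, as the exact permutation p of the summed CPM was 0.0476. This stays a hypothesis, since features and test were chosen on the same values.

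Replicate C of silenced and of rescued stood apart from replicates A and B, with first principal component scores of 45.9 and 27.9 against -3.03 to 11.2. Library depth gave no single answer, because rescued C held 10790925 reads, more than the 2 other rescued libraries, and silenced C held 7528097, the fewest of all 9. Unequal numbers of reads are argued against, because with all libraries thinned to 7528097 reads the distance of C from A and B on that component was 98.3% of the former one in silenced and 100.4% in rescued libraries. GC content or transcript length is argued against too, because the correlation of the silenced and rescued C deviations across genes was 0.584 before and 0.602 after both were regressed out. This does not extend to parental C, where both explained 27.2% of the variance of the deviation, beside 1.77% in silenced C and 4.24% in rescued C. A culture or preparation day shared by silenced C and rescued C, whose deviations correlated at 0.584, could contribute and stays open. The deposited sample numbers pair silenced and rescued libraries by letter and set the parental ones apart. The correlations of the parental C deviation with the others, 0.219 and 0.105, therefore do not decide the question. The labels do not say what a letter marks. No biological explanation was tested for the distance of replicate C.

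The libraries were also split otherwise, and the numbers of splits that reached a real count include the real split. For genes changed, 3 against 3 libraries make 10 splits, too few for a share under 0.05. In silenced against parental 1 split, the real one, gave 2446 genes (highest other 0), and in rescued against parental 1, the real one, gave 1381 (highest other 0). In silenced against rescued 2 splits, the real one among them, gave the real 3 or more, and the highest other gave 296. That split set silenced A with rescued A and B against silenced B and C with rescued C, and its count points to a structure of the samples. Since letters paired these libraries, the real split was compared with the 3 others that part all 3 pairs, which gave 0 genes. These are too few for a share under 0.05, and each of them mixes libraries with low and high C6orf203 by design. For mtDNA-encoded mRNAs 10 of 10 splits gave a count of 0 or more in each comparison (real 0, highest other 0). A real count of 0 fixes that outcome in advance, so it decides nothing. For lists, 3 splits reached the real 12 in silenced against parental, 7 the real 6 in silenced against rescued and 6 the real 10 in rescued against parental (highest other 13 each). For genes changed against both controls 4 of 100 splits of the 9 libraries, the real one among them, gave the real 3 or more (highest other 1412). The others that did so set the parental libraries against the engineered ones. Their counts, from 877 to 1412, therefore hold the difference between those lines. Of the 100 splits 94 mixed parental and engineered libraries in a way that gave 0 genes, so the share of 4 in 100 decides nothing. Only 20 splits keep the parental libraries as 1 control group, too few for a share under 0.05. Of these 3 gave the real 3 or more, and the highest other gave 266, with silenced B and C and rescued C set together, which points to a structure of the samples.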

How the results depend on the processing

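The omission of replicate C of both engineered lines, the fit of 2 groups with a replicate block and the estimated correlation with a replicate block were chosen only after the results were seen. C6orf203 kept its direction and its call in every alternative run (log2 -1.45 to -0.97, -3.59 to -2.95 and 1.95 to 2.38). Of the named genes 47 of 90 in silenced against parental, 29 of 60 in rescued against parental and 5 of 9 in silenced against rescued kept both in every alternative; of their single values 1935 of 2158, 1282 of 1439 and 205 of 225 did. Among them MT-ND2 alone turned, with quantile normalization, to 0.0158 (MT-ND2, silenced vs parental) and 0.0242 (MT-ND2, rescued vs parental). The cause was not tested for any change given here, except that stricter thresholds call fewer genes by construction. At the present depth and 3 libraries per group limma called a minority of the changes simulated at a log2 fold of 0.5, and the annotated mtDNA features outside the table cannot be assessed.

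With the replicate block 4800 genes changed in silenced against parental, 22 in silenced against rescued, 3602 in rescued against parental and 16 against both controls. It called 1 mtDNA-encoded mRNA in silenced against parental and 1 in rescued against parental, and 12, 7 and 11 lists in the 3 comparisons. More members of lists were called in the comparisons with parental, among them 50 and 36 lower mitoribosomal proteins, 8 and 6 complex I subunits and 13 and 5 complex II to V subunits in silenced and rescued cells, and none in silenced against rescued. The letters did not pair parental libraries with silenced (0.00, -0.02 and 0.11 for A, B and C) or rescued ones (0.02, 0.13 and 0.22), and only letter C, and letters B and C, correlated best with their own letter. With the 2 groups alone and the block, silenced against rescued gave 284 genes and 1 mtDNA-encoded mRNA. Library quality weights gave 6286, 872 and 3922 genes, 481 against both controls, and 1 mtDNA-encoded mRNA in silenced against parental and in silenced against rescued. DESeq2 called 7 genes in silenced against rescued and 1 mtDNA-encoded mRNA in silenced against parental. A constant prior variance gave 828 genes in rescued against parental. Without replicate C of both engineered lines the counts were 10 in silenced against rescued, 2584 in rescued against parental and 5 against both controls. A minimum of 1 on the log2 scale left 420 and 231 genes, and an adjusted p under 0.01 left 640 and 321, in silenced and rescued against parental. Leaving out each library gave 1004 to 3361, 2 to 4 and 487 to 2378 genes in the 3 comparisons, 6 to 12 lists in silenced against rescued, 5 to 11 in rescued against parental, and a silenced minus rescued mtDNA share of -2.34 to 0.788 points. Camera with an estimated correlation, fry, and the estimated correlation with the block called 0 lists in each comparison.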

Other observations

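All values in this part were chosen for description only after the results were seen.

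The replicate C libraries of both engineered lines had lower levels of several lists, among them genes for lipid and sugar metabolism, than replicates A and B of the same line. The median log2 difference of cholesterol synthesis genes was -0.61 in silenced C and -0.56 in rescued C, beside -0.18 in parental C. Glycolysis genes had medians of -0.41 and -0.63, beside -0.17 in parental C. G1/S genes had medians of -0.36 and -0.43, beside -0.26. The fall was not particular to these lists. Complex I subunits had medians of -0.45 and -0.33, beside -0.11, and complex II to V subunits of -0.48 and -0.29, beside -0.13. Some lists went the other way, such as integrated stress response genes (0.44 and 0.13). Nuclear protein-coding genes took 63.0% of CPM in silenced C, beside 66.9% and 68.0% in silenced A and B. They took 59.1% in rescued C, beside 67.4% and 66.6% in rescued A and B. Each value compares 1 library with 2 and was not tested.

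Small nuclear and nucleolar RNAs took 3.18 ± 0.586% of CPM in parental, 3.52 ± 0.444% in silenced and 4.16 ± 0.599% in rescued libraries (SD, n = 3). Nuclear protein-coding genes took 69.1 ± 1.88%, 65.98 ± 2.61% and 64.4 ± 4.55%. For silenced against parental, silenced against rescued and rescued against parental the exact permutation p was 0.5, 0.3 and 0.2 for the former and 0.2, 0.6 and 0.2 for the latter, where 3 against 3 libraries allow none below 0.1.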
